A study of Homo sapiens with 5 samples.

How the data were processed

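RNA of COV434 cells was sequenced in 5 libraries, 2 from control cells and 3 from cells given 3-nitropropanoic acid (3-NP). Groups and replicate numbers were taken from the sample titles. The labels give no dose, time, culture condition or harvest date for either group. They name COV434 in every title, while the cell line and source fields count upward from COV434 to COV438 over the 5 samples, and all were taken as COV434. Nothing in the labels says that libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical.

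Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a strand-specific mRNA kit. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.39, HISAT2 2.1 and the build GRCh38 (hg38). The read counter, its annotation, its strand setting and its handling of reads with several positions are not given in the sources used here. Genes that share reads with near-identical copies or overlap others are therefore uncertain, and antisense pairs cannot be separated with certainty. Each deposited file lists 1 value per Ensembl gene in 1 library. The unit is not written in the files. The values deposited by the authors were read as FPKM. They are not whole, their totals of 262081 to 299515 differ between libraries, and value times gene length gives whole multiples of 1 step per library. Whether reads or read pairs were counted is not stated, and "reads" is used here.

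The files held 30631 genes, 1688 of them at 0 in every library. Of these 30390 were found in GENCODE 29 and 24336 in a table of current symbols, and 17105 were protein-coding. With exon-union lengths from GENCODE 29, 93.1% to 93.3% of values above 0 came to a whole number of reads within 0.05 read, which gave depths of 18753000, 17838000, 18883000, 18653000 and 18831000 reads for control replicates 1 and 2 and 3-NP replicates 1, 2 and 3. On a gene of 2 kb, 3 reads corresponded to 0.0794 to 0.0841 FPKM, the level that a value of 0 allows. This covers counting error only, and differences near it were not detectable at this depth.

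A count-based test had been planned for count files. Because the files hold FPKM, the alternative set out in the same plan was used. It was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(FPKM + 1), for genes at 1 FPKM or more in at least 2 libraries. The group was the only term, all 5 libraries entered, and p-values were adjusted by Benjamini-Hochberg at 0.05. Fold changes on this scale understate changes of low genes. A gene called at least 2-fold had a fitted log2 change of 1 or more in size. The 5 libraries left 3 residual degrees of freedom. No 2 libraries held identical columns.

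In all, 42 gene lists covering 816 genes (29 of them in more than 1 list) were fixed before the data were examined, among them markers of other cell types, and the 37 with 5 or more tested genes were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera rests on the 3 residual degrees of freedom, so hardly any list could pass it. Adjusted p-values are over the 37 lists, and counts adjusted over the list alone are also given. Named genes followed a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls among called protein-coding genes with a mean of 1 FPKM or more and groups that did not overlap. It took SDHA, SDHB, SDHC, SDHD, SMARCA4, SMARCA2 and FOXL2 whatever their result. It also took up to 3 called members with the smallest p from each list that was called or had at least 3 called members. This gave 113 genes. Other genes named in the report complete a count of 5 or fewer or, like MT2A, were singled out. These and the genes of the closing section were picked after their values were seen. A few genes and 1 of the lists are not reported here.

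The fit was tested on simulated data for the comparison of 3-NP with control (200 genes changed before the filter, 11510 genes passing it). It recovered 87.76% of 2-fold rises, 100% of 4-fold rises, 82.98% of falls to 0.5 and 100% of falls to 0.25. There were 180 true calls and 24 false calls, the latter among 11316 unchanged genes. In this single draw false calls thus made up a larger share of all calls than the threshold on adjusted p-values is meant to allow. The simulation used a dispersion of 0.02, which was set and not estimated. It changed only 200 genes, while 40.76% of the genes tested were called in the data. The share of false calls in the data cannot be read from it. Alternatives chosen in advance were quantile normalization, no low-value filter, a stricter filter (2 FPKM in every library of 1 group), a pseudocount of 0.1, mitochondrially encoded genes left out, the replicate number as a block, and each library left out in turn. Added after the results were seen were equal FPKM totals, median-of-ratios scaling, robust variance moderation, protein-coding genes only and voom on reads worked out from FPKM. Also added then was removal of trends with length or with length and GC content by splines, which also recentres each library. Length there is the exon-union length of the gene, not that of the transcripts expressed. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for joining and for Fisher's exact tests, and matplotlib 3.10.9 for figures. Coordinates are from GENCODE 29 on GRCh38.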

Results

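Messenger RNA was sequenced from COV434 cells, a cell line described in the labels as derived from a human ovarian granulosa cell tumour. Cells given 3-nitropropanoic acid (3-NP), which irreversibly inhibits succinate dehydrogenase (complex II of the respiratory chain), were set against control cells. There were 2 control libraries and 3 libraries of 3-NP cells. Levels were given as FPKM (reads scaled for gene length and library depth) for 30631 genes. The depth worked out from these values was 18753000 and 17838000 reads in the control libraries. In the 3-NP libraries it was 18883000, 18653000 and 18831000 reads. Across the 11858 genes tested, log2(FPKM + 1) correlated at r = 0.9854 between the controls and at 0.9678 to 0.9821 among the 3-NP libraries. Between a control and a 3-NP library r was 0.8907 to 0.91. These correlations are across genes, which are not independent replicates. Mitochondrial ribosomal RNA made up 0.639% and 0.734% of reads in the controls and 1.04%, 1.5% and 1.31% in the 3-NP libraries. Values below are means ± SD over 2 control and 3 3-NP libraries, and fold changes are on the log2(FPKM + 1) scale with limma's adjusted p.

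The comparison asked which transcripts differ between COV434 cells with and without 3-NP. In 3-NP cells, transcripts for the chemokine CCL20, the lipoprotein lipase inhibitor ANGPTL4 and the early response gene IER3 had the largest rises, and those for the actin-binding protein NEXN, the oxytocin receptor OXTR and the keratin KRT18 the largest falls, by fitted change on log2(FPKM + 1) among genes with a mean of 1 FPKM or more, a scale that ranks genes of low control level down. CCL20 (chromosome 2, positions 227805739 to 227817564, GRCh38) went from 4.31 ± 0.642 to 271 ± 26.3 FPKM, a ratio of 63 (log2 fold change 5.68 ± 0.16 SE, adjusted p = 1.84e-05). ANGPTL4 (chromosome 19, positions 8363289 to 8374373) went from 4.79 ± 0.637 to 259 ± 40.1 FPKM (log2 fold change 5.48 ± 0.18 SE, adjusted p = 2.14e-05). IER3 went from 7.76 ± 0.901 to 217 ± 8.39 FPKM (log2 fold change 4.64 ± 0.14 SE, adjusted p = 1.92e-05). The next largest rises were in DUSP5, a phosphatase of ERK (4.32), the protease inhibitor TFPI2 (4.1), the transcription factor EGR1 (4.08), the EGF receptor ligand AREG (3.93) and the proteoglycan SDC4 (3.92), as log2 fold changes. NEXN (chromosome 1, positions 77888513 to 77943895) went from 29.2 ± 2.03 to 1.76 ± 0.357 FPKM, 16.6 times lower (log2 fold change −3.46 ± 0.16 SE, adjusted p = 8.33e-05). OXTR went from 76.1 ± 5.36 to 7.15 ± 2.39 FPKM (log2 fold change −3.28 ± 0.24 SE, adjusted p = 0.000284). KRT18 went from 421 ± 55.1 to 47.5 ± 12.7 FPKM (log2 fold change −3.15 ± 0.24 SE, adjusted p = 0.000318), a value made uncertain by the many near-identical KRT18 pseudogenes. Falls also passed the test in the adhesion protein AMIGO2 (−3.07), the interferon-induced IFIT3 (−2.94), prostacyclin synthase PTGIS (−2.93), the decoy receptor TNFRSF11B (−2.87) and the endocytic adaptor DAB2 (−2.81). In all, 4833 genes passed an adjusted p of 0.05, of which 1842 were higher and 2991 lower in 3-NP cells, and 598 and 876 of these differed at least 2-fold. Libraries of the 2 groups did not overlap in any of the 4833, nor in 64.22% of all genes tested, against 20% by chance. Lower calls made up 61.89%, against 51.73% with a trend with exon-union gene length removed, which also recentres each library, and 68.93% with equal FPKM totals. Without control replicate 1, 752 genes were higher and 1062 lower, and without control replicate 2, 909 and 1179, while 444 of the 4833 fell under the low-value filter in each of these fits.

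**Figure D1:**
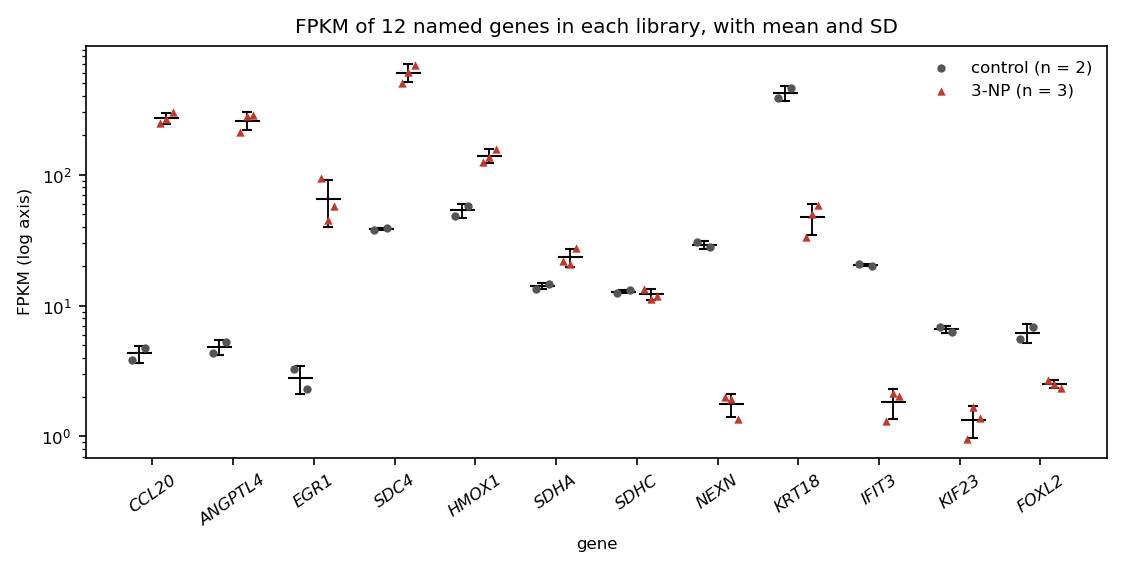
FPKM on a log axis for 12 named genes in each library, with circles for the 2 control libraries, triangles for the 3 libraries of 3-NP cells, and horizontal marks and bars for the mean and SD. All 3-NP libraries lie above both controls for CCL20, ANGPTL4, EGR1, SDC4, HMOX1 and SDHA and below both for NEXN, KRT18, IFIT3, KIF23 and FOXL2, while SDHC overlaps.

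Transcripts of complex II, the target of 3-NP, were higher for most catalytic and anchor subunits. The flavoprotein subunit SDHA (chromosome 5, positions 218241 to 256700) went from 14 ± 0.745 to 23.4 ± 3.81 FPKM (log2 fold change 0.69 ± 0.16 SE, adjusted p = 0.014). The iron-sulfur subunit SDHB went from 30.05 ± 3.78 to 42.6 ± 1.75 FPKM (log2 fold change 0.49 ± 0.14 SE, adjusted p = 0.029). The membrane anchor SDHD went from 15.5 ± 0.113 to 25.1 ± 2.37 FPKM (log2 fold change 0.66 ± 0.14 SE, adjusted p = 0.00921). SDHC, the other anchor, was 12.8 ± 0.356 FPKM in control and 12.2 ± 1.12 FPKM in 3-NP cells (log2 fold change −0.07 ± 0.14 SE, adjusted p = 0.72). Without control replicate 1 the adjusted p was 0.106 for SDHA, 0.237 for SDHB and 0.0706 for SDHD, and without control replicate 2 it was 0.0681, 0.0702 and 0.0697. SDHB also lost the call without 3-NP replicate 2 (0.0698) or 3 (0.0727), without a low-value filter (0.0512) and with the replicate number as a block (0.0853). Of the 8 complex II genes and assembly factors tested, 4 rose, the last being SDHAF3 (adjusted p = 0.0554 without control replicate 1), and none fell (4 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.06). For the complex II list adjusted p = 0.628 with an estimated correlation. With the preset correlation it passed without 3-NP replicate 2 (camera adjusted p = 0.0472), after quantile normalization (0.0408), with no or a stricter low-value filter (0.0236 and 0.0246) and with equal FPKM totals (0.0499). Nuclear-encoded subunits of oxidative phosphorylation had a median change of 0.22 and were called higher as a list, although only 6 of 63 rose and 4 fell (0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.013). For that list adjusted p = 0.82 with an estimated correlation, and the call was lost without control replicate 1, where the median was 0.016 (camera adjusted p = 0.648), and without 3-NP replicate 3, where it was 0.13 (0.086). It was also lost after quantile normalization (0.0546) and after removal of the length trend (0.0885) or the length and GC trends (0.0632). Among the falls were the complex I subunits NDUFC2 (−0.80) and NDUFS1 (−0.53). Both no longer passed without control replicate 1 (adjusted p = 0.0784 and 0.137) or 2 (0.051 and 0.0718), nor did NDUFS1 with the length (0.115) or the length and GC trends removed (0.149). None of the 13 mitochondrially encoded subunits passed the test (median −0.22, camera adjusted p = 0.67, and 0.0408 after quantile normalization). Among 18 TCA cycle genes 2 rose, pyruvate carboxylase PC (1.34) and IDH2 (0.69), and IDH2 had adjusted p = 0.0708 without control replicate 1 and 0.0505 without control replicate 2. Among 13 mitochondrial chaperones and proteases TRAP1 rose (0.48) and CLPX fell (−0.55), and leaving out control replicate 1 ended both calls (adjusted p = 0.232 and 0.186), as did leaving out control replicate 2 (0.0823 and 0.0619). Without 3-NP replicate 2 or 3 TRAP1 had adjusted p = 0.0585 and 0.0845. Among 17 genes of mitochondrial biogenesis, dynamics and mitophagy 1 rose and 3 fell. In this list ESRRA, a nuclear receptor of mitochondrial gene control, went from 13.3 ± 2.26 to 29 ± 2.49 FPKM (log2 fold change 1.08 ± 0.16 SE, adjusted p = 0.0025). The fusion protein MFN2 went from 32.1 ± 0.303 to 21.5 ± 1.44 FPKM (log2 fold change −0.56 ± 0.13 SE, adjusted p = 0.014). MFN2 no longer passed without control replicate 1 (adjusted p = 0.105) or 2 (0.09), or without 3-NP replicate 2 (0.0509). The other falls, in POLG and FUNDC1, had adjusted p = 0.045 and 0.043, and 0.175 and 0.154 without control replicate 1. Fits without control replicate 2 or 3-NP replicate 2 or 3 also ended both, and the fit without 3-NP replicate 1 ended POLG (0.0516). FUNDC1 was lost as well after quantile normalization (0.0819), without a low-value filter (0.0709), with median-of-ratios scaling (0.108) and with voom (0.0654).

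Cell cycle transcripts fell together. Of 26 genes of G2/M and mitosis 20 fell and none rose (median −1.24, 0 higher and 21 lower adjusted over the list alone, camera adjusted p = 1.89e-05). With an estimated correlation the list had adjusted p = 0.634. The mitotic kinesin KIF23 went from 6.56 ± 0.38 to 1.34 ± 0.366 FPKM (log2 fold change −1.7 ± 0.17 SE, adjusted p = 0.000721). Its relative KIF20A went from 5.78 ± 0.605 to 1.08 ± 0.516 FPKM (log2 fold change −1.74 ± 0.23 SE, adjusted p = 0.00181). Cyclin CCNB2 went from 5.73 ± 0.327 to 1.5 ± 0.495 FPKM (log2 fold change −1.45 ± 0.20 SE, adjusted p = 0.00188). Of 24 genes of G1/S and DNA replication 17 fell and 1 rose (median −0.84, 1 higher and 18 lower adjusted over the list alone, camera adjusted p = 0.000221), with adjusted p = 0.628 with an estimated correlation. UHRF1, a maintenance factor of DNA methylation, went from 6.01 ± 0.141 to 1.37 ± 0.233 FPKM (log2 fold change −1.57 ± 0.15 SE, adjusted p = 0.000559), and the replicative helicase subunits MCM3 and MCM4 changed by −1.68 and −1.53. Ribosome biogenesis and MYC targets also fell, with 15 of 24 lower and 3 higher (median −0.69, 3 higher and 15 lower adjusted over the list alone, camera adjusted p = 0.013). For these adjusted p = 0.628 with an estimated correlation. The nucleolar protein NOP56 went from 17.6 ± 2.6 to 3.93 ± 0.0924 FPKM (log2 fold change −1.9 ± 0.14 SE, adjusted p = 0.000309). The RNA polymerase I subunit POLR1A went from 5.77 ± 0.925 to 1.21 ± 0.287 FPKM (log2 fold change −1.62 ± 0.17 SE, adjusted p = 0.000819). ODC1, the first enzyme of polyamine synthesis, rose from 50.3 ± 2.52 to 187 ± 35.5 FPKM (log2 fold change 1.85 ± 0.19 SE, adjusted p = 0.000753). Ribosomal proteins were shifted up as a list of 44 (median 0.45, camera adjusted p = 3.21e-05), but singly 5 rose and 1 fell (0 higher and 0 lower adjusted over the list alone), and adjusted p = 0.691 with an estimated correlation. Their median log2(FPKM + 1) was 7.17 and 7.46 in the controls and 7.43, 7.89 and 8.1 in 3-NP cells, so the lowest 3-NP library lay below the higher control. Reads of ribosomal protein genes can be shared with their pseudogenes.

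Immediate early genes, which growth factors and stress induce within the hour, formed the list with the smallest p by camera with the preset correlation. The NF-kB and inflammatory list had the smallest unadjusted p by fry (7.93e-05, against 0.000251 for immediate early genes). It also had the smallest by camera with an estimated correlation (0.0256 against 0.045). Of 18 genes 16 rose and 1 fell (median 1.43, 16 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.23e-09). For the list adjusted p = 0.366 with an estimated correlation. The 1 that fell was MYC (−0.97, adjusted p = 0.00257). FOS went from 0.363 ± 0.023 to 10.3 ± 1.03 FPKM (log2 fold change 3.05 ± 0.14 SE, adjusted p = 8.33e-05). The ERK phosphatase DUSP6 went from 0.68 ± 0.0658 to 8.77 ± 0.947 FPKM (log2 fold change 2.54 ± 0.15 SE, adjusted p = 0.000179). EGR1 went from 2.79 ± 0.689 to 65.5 ± 25.8 FPKM (log2 fold change 4.08 ± 0.30 SE, adjusted p = 0.000289). Among 18 NF-kB and inflammatory genes 10 rose and 3 fell (median 1.04, 10 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.000684). With an estimated correlation this list had adjusted p = 0.366. Beside CCL20, the adhesion molecule ICAM1 went from 4.59 ± 0.37 to 17.2 ± 1.52 FPKM (log2 fold change 1.71 ± 0.14 SE, adjusted p = 0.000393). The apoptosis inhibitor BIRC3 went from 3.74 ± 0.731 to 24.1 ± 7.22 FPKM (log2 fold change 2.38 ± 0.24 SE, adjusted p = 0.000706). Interferon-stimulated genes fell, with 13 of 20 lower and 1 higher (median −1.18, 1 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.000221). Their adjusted p was 0.628 with an estimated correlation. IFIT1 went from 20.3 ± 0.937 to 2.96 ± 0.427 FPKM (log2 fold change −2.43 ± 0.15 SE, adjusted p = 0.000179). IFIT2 went from 9.77 ± 0.945 to 0.555 ± 0.228 FPKM (log2 fold change −2.8 ± 0.17 SE, adjusted p = 0.000185). IFIT2 was under the low-value filter, and not tested, with a control left out. In the list of WNT and NOTCH targets, of which 6 of 14 genes could be tested, 5 rose (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.011), with adjusted p = 0.366 with an estimated correlation. The 5 were all genes of the NOTCH pathway, HEY1, HES1, HES4, NRARP and NOTCH3, while the WNT feedback gene ZNRF3 had a log2 fold change of −0.34 (adjusted p = 0.086 over all genes) and was the 1 lower adjusted over the list alone. HES4 lost the call without a low-value filter (adjusted p = 0.0562) and with length and GC trends removed (0.0733). Leaving out control replicate 1 ended the calls of HES4 (adjusted p = 0.109), NRARP (0.181) and NOTCH3 (0.0819), and leaving out control replicate 2 those of NRARP (0.0683) and NOTCH3 (0.0733). HEY1 went from 0.291 ± 0.178 to 2.71 ± 0.358 FPKM (log2 fold change 1.52 ± 0.16 SE, adjusted p = 0.000835). HES1 went from 0.702 ± 0.0314 to 3.85 ± 0.687 FPKM (log2 fold change 1.5 ± 0.16 SE, adjusted p = 0.000864). Among 14 YAP/TEAD targets 3 rose, with ANKRD1 going from 446 ± 14.3 to 1428 ± 119 FPKM, and 7 fell, with AJUBA going from 22.1 ± 0.389 to 4.97 ± 0.465 FPKM (camera adjusted p = 0.17). The list passed after quantile normalization (0.0408) and without a low-value filter (0.0372). Among 14 TGF-beta and BMP targets 3 rose, among them PMEPA1 (1.68) and SMAD7 (1.13), and 5 fell, among them ID2 (−1.39). The list had camera adjusted p = 0.99.

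**Figure D2:**
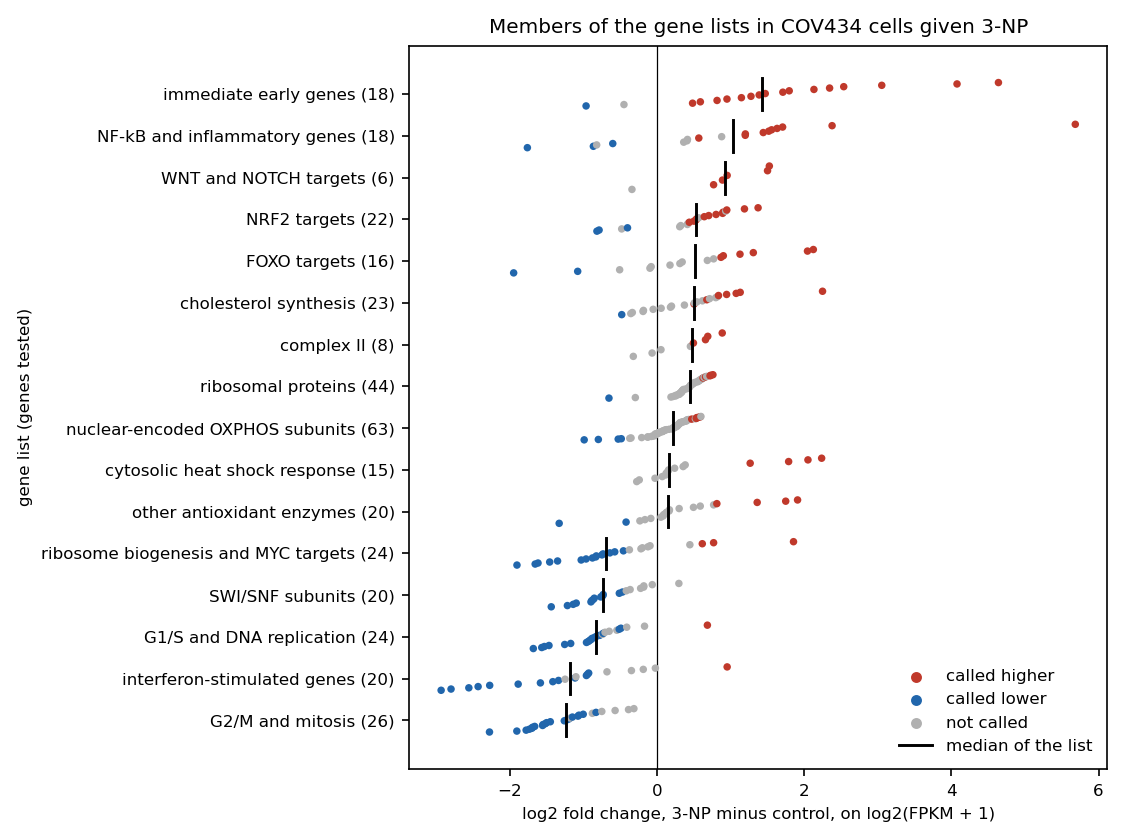
Fitted log2 fold changes (3-NP minus control, on log2(FPKM + 1)) of the tested members of the 15 gene lists that camera called, and of complex II, which it did not call. Points are genes, coloured by whether they were called higher, lower or not called, black bars are list medians, and numbers in parentheses are genes tested. Medians run from −1.24 for G2/M and mitosis to 1.43 for immediate early genes.

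Of the stress lists, targets of NRF2, the regulator of antioxidant genes, rose. Of 22 genes 12 rose and 3 fell (median 0.53, 15 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.000571). For the list adjusted p = 0.544 with an estimated correlation. Heme oxygenase HMOX1 went from 53.2 ± 6.82 to 139.5 ± 17.3 FPKM (log2 fold change 1.37 ± 0.17 SE, adjusted p = 0.00128). The ferritin light chain FTL went from 2073 ± 364 to 4692 ± 347 FPKM (log2 fold change 1.19 ± 0.20 SE, adjusted p = 0.00421). AKR1C1, which shares reads with AKR1C2, went from 5.27 ± 0.544 to 9.92 ± 0.725 FPKM (log2 fold change 0.80 ± 0.14 SE, adjusted p = 0.00459). AKR1C1 had adjusted p = 0.0534 without control replicate 1, and FTL 0.0748 without a low-value filter. Among 20 other antioxidant enzymes 4 rose and 2 fell (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.041), with adjusted p = 0.628 with an estimated correlation. This call was lost without control replicate 1 (camera adjusted p = 0.182) and without 3-NP replicate 3 (0.0667), after quantile normalization (0.0948) and after removal of the length trend (0.0885) or the length and GC trends (0.0821). It was lost as well with the stricter low-value filter (0.0567), protein-coding genes only (0.0555) and voom (0.0735). Glutaredoxin GLRX went from 13.3 ± 1.88 to 52.6 ± 1.19 FPKM (log2 fold change 1.91 ± 0.14 SE, adjusted p = 0.000301). Glutathione peroxidase GPX3 went from 5.19 ± 0.208 to 19.8 ± 2.03 FPKM (log2 fold change 1.75 ± 0.14 SE, adjusted p = 0.000384). GPX8 fell from 39.6 ± 4.31 to 15.1 ± 1.36 FPKM (log2 fold change −1.33 ± 0.15 SE, adjusted p = 0.000916). Among 15 heat shock genes 4 rose and none fell (4 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.016), with adjusted p = 0.366 with an estimated correlation and 0.0882 after quantile normalization. The co-chaperone DNAJB1 went from 43 ± 3.86 to 207 ± 25.7 FPKM (log2 fold change 2.24 ± 0.16 SE, adjusted p = 0.000287). The near-identical HSPA1A and HSPA1B changed by 1.79 and 2.05, and their reads cannot be told apart with certainty. HSPA1A had adjusted p = 0.0536 without control replicate 1. Of 8 metallothioneins in the fixed list 4 could be tested, too few for the list test, and all 4 rose. MT1X and MT1A, at most 0.0301 and 0.135 FPKM in the controls, passed the low-value filter only through the 3-NP libraries. Only a rise could have been seen in these. MT2A went from 455 ± 74.4 to 1720.5 ± 70.8 FPKM (log2 fold change 1.93 ± 0.18 SE, adjusted p = 0.00054). MT1E lost the call without control replicate 1 (adjusted p = 0.125) or 2 (0.0954), or without 3-NP replicate 2 (0.0625).

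Among 22 genes of the endoplasmic reticulum unfolded protein response 2 rose and 1 fell. They were the stress sensor ERN1 (0.93, adjusted p = 0.00251), the chaperone HSPA5 (1.89, adjusted p = 0.017) and XBP1, which went from 44.9 ± 3.54 to 18.7 ± 4.81 FPKM (log2 fold change −1.25 ± 0.22 SE, adjusted p = 0.00475). HSPA5 stood at 222 and 218 FPKM in the controls and at 385, 1140 and 1257 FPKM in the 3-NP libraries. Its adjusted p was 0.0788 without control replicate 1 and 0.076 without control replicate 2, and 0.0917 without a low-value filter. The list was called higher only without 3-NP replicate 1 (camera adjusted p = 0.0136), against 0.094 with all libraries. Targets of ATF4 in the integrated stress response split, with 7 of 29 higher and 9 lower (median −0.34, camera adjusted p = 0.99). ATF3 went from 2.44 ± 0.0769 to 29.4 ± 4.99 FPKM (log2 fold change 3.13 ± 0.17 SE, adjusted p = 0.000167). ATF5 went from 6.16 ± 0.113 to 1.04 ± 0.187 FPKM (log2 fold change −1.81 ± 0.14 SE, adjusted p = 0.000366). Of 20 cytosolic aminoacyl-tRNA synthetases 5 fell and 1 rose (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.076). The list passed after quantile normalization (0.0194), without a low-value filter (0.0057) and with equal FPKM totals (0.0465). Of 24 targets of hypoxia-inducible factor 8 rose and 6 fell (camera adjusted p = 0.21), among them NDRG1 from 2.66 ± 0.154 to 22.9 ± 2.05 FPKM (log2 fold change 2.71 ± 0.14 SE, adjusted p = 0.000138). STC2 went from 58.3 ± 2.48 to 21.1 ± 3.54 FPKM (log2 fold change −1.44 ± 0.17 SE, adjusted p = 0.00121).

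Genes of cell death and survival moved both ways. Of 20 pro-apoptotic genes 7 rose and 6 fell (10 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.33). The BH3-only gene BCL2L11 went from 0.745 ± 0.113 to 4.28 ± 0.669 FPKM (log2 fold change 1.59 ± 0.16 SE, adjusted p = 0.000736). The BH3-only gene PMAIP1 went from 26.7 ± 1.87 to 91.4 ± 4.4 FPKM (log2 fold change 1.74 ± 0.14 SE, adjusted p = 0.000345). The death receptor FAS went from 15.8 ± 1.17 to 3.29 ± 0.944 FPKM (log2 fold change −1.99 ± 0.20 SE, adjusted p = 0.000721). Of 9 anti-apoptotic genes 3 rose and 4 fell (3 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.82). BCL2L1, which encodes BCL-XL, went from 56.8 ± 4.91 to 16.1 ± 1.88 FPKM (log2 fold change −1.76 ± 0.15 SE, adjusted p = 0.00045). CFLAR, an inhibitor of caspase activation at death receptors, went from 3.3 ± 0.499 to 0.983 ± 0.0154 FPKM (log2 fold change −1.11 ± 0.14 SE, adjusted p = 0.00159). With a control left out CFLAR was under the low-value filter and was not tested. Of 24 autophagy and lysosome genes 6 rose and 6 fell (camera adjusted p = 0.14). The autophagy kinase ULK1 went from 11.1 ± 0.574 to 31.3 ± 6.54 FPKM (log2 fold change 1.4 ± 0.19 SE, adjusted p = 0.00193), and GABARAPL1 changed by 0.87. FOXO targets were called higher, with 6 of 16 up and 2 down (median 0.51, 8 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.031). For these adjusted p = 0.628 with an estimated correlation, and the call was lost without control replicate 2 (camera adjusted p = 0.0772) and without 3-NP replicate 1 (0.07), and with the stricter low-value filter (0.126). GADD45B went from 35.4 ± 3.35 to 157 ± 10.03 FPKM (log2 fold change 2.12 ± 0.14 SE, adjusted p = 0.000243). The repressor BCL6 went from 3.21 ± 0.173 to 16.4 ± 2.36 FPKM (log2 fold change 2.04 ± 0.16 SE, adjusted p = 0.000318). The thioredoxin inhibitor TXNIP went from 53.6 ± 2.05 to 13.4 ± 3.64 FPKM (log2 fold change −1.95 ± 0.21 SE, adjusted p = 0.00088).

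Among metabolic lists, cholesterol synthesis was higher, with 7 of 23 genes up and 1 down (median 0.51, 6 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.011). With an estimated correlation it had adjusted p = 0.366. Squalene synthase FDFT1 went from 19.9 ± 2.73 to 44.8 ± 4.15 FPKM (log2 fold change 1.13 ± 0.15 SE, adjusted p = 0.002). MSMO1 went from 25.3 ± 1.51 to 49.8 ± 4.18 FPKM (log2 fold change 0.94 ± 0.14 SE, adjusted p = 0.00268). Of 20 glycolysis genes 2 rose, both glucose transporters, and 2 fell (camera adjusted p = 0.38). SLC2A3 went from 9.46 ± 0.506 to 42.6 ± 6.62 FPKM (log2 fold change 2.05 ± 0.17 SE, adjusted p = 0.000384). SLC2A1 changed by 0.82 and hexokinase HK2 by −0.62, and both lost the call without control replicate 1 (adjusted p = 0.0723 and 0.124) or 2 (0.0595 and 0.0667). Of 13 genes of fatty acid synthesis and desaturation 3 rose and 3 fell (camera adjusted p = 0.67), with ACSL3 going from 8.79 ± 0.682 to 29.1 ± 3.95 FPKM (log2 fold change 1.61 ± 0.16 SE, adjusted p = 0.000636). ELOVL6 went from 6.13 ± 0.562 to 2.46 ± 0.706 FPKM (log2 fold change −1.06 ± 0.19 SE, adjusted p = 0.005). Of 14 genes of fatty acid oxidation ETFA and ETFDH rose and CPT1A fell (camera adjusted p = 0.16), and all 3 calls were lost without control replicate 1 (adjusted p = 0.155, 0.0961 and 0.115) or 2 (0.0883, 0.0887 and 0.0782). ETFA also lost it without 3-NP replicate 2 (0.0539) or 3 (0.0568), and without a low-value filter (0.0565).

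Granulosa genes, chromatin remodelling subunits and markers of other cell types were then examined, and no cell type was assigned from them. FOXL2, a transcription factor of granulosa cells, went from 6.2 ± 0.988 to 2.51 ± 0.188 FPKM (log2 fold change −1.03 ± 0.15 SE, adjusted p = 0.00236). The activin antagonist FST went from 8.95 ± 0.165 to 2.31 ± 0.703 FPKM (log2 fold change −1.61 ± 0.19 SE, adjusted p = 0.00113). The inhibin subunit INHBB went from 4.85 ± 0.0149 to 2.26 ± 0.077 FPKM (log2 fold change −0.85 ± 0.13 SE, adjusted p = 0.00289). Of 20 granulosa markers 11 could be tested, and 4 fell and none rose (median 0.10, 0 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.85). The median lay on the other side of 0 from the falls. The remaining fall, in IRX5 (−0.42, adjusted p = 0.0496), no longer passed without control replicate 1 (0.146) or 2 (0.305), or without 3-NP replicate 2 (0.111) or 3 (0.108). Of 6 steroidogenic genes tested 4 rose and 1 fell (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.094, and 0.0229 without a low-value filter). For the list adjusted p = 0.628 with an estimated correlation. The 1 that fell was the steroidogenic regulator NR5A1, which went from 23.4 ± 2.13 to 12.8 ± 1.37 FPKM (log2 fold change −0.82 ± 0.15 SE, adjusted p = 0.00528). NR5A1 had adjusted p = 0.0548 without control replicate 2. The 4 that rose, FDX1, FDXR, POR and SCARB1, changed by 0.64, 0.78, 0.48 and 0.52, and none passed without control replicate 1 (lowest adjusted p 0.0885) or 2 (lowest 0.0522). SWI/SNF chromatin remodelling subunits fell, with 13 of 20 lower and none higher (median −0.74, 0 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.00133), and adjusted p = 0.366 with an estimated correlation. SMARCB1 went from 22.8 ± 2.4 to 7.83 ± 1.34 FPKM (log2 fold change −1.44 ± 0.17 SE, adjusted p = 0.00113), and BRD9 changed by −1.22. Of the ATPases, SMARCA4 was 12.6 ± 0.168 FPKM in control and 6.65 ± 1.6 FPKM in 3-NP cells (log2 fold change −0.85 ± 0.19 SE, adjusted p = 0.01) and SMARCA2 3.62 ± 0.696 FPKM in control and 2.46 ± 0.544 FPKM in 3-NP cells (log2 fold change −0.42 ± 0.18 SE, adjusted p = 0.11). SMARCA4 had adjusted p = 0.0645 without control replicate 1 and 0.0648 without control replicate 2, and SMARCA2 passed without 3-NP replicate 1 (0.0463). Of 19 extracellular matrix and mesenchymal genes 9 fell and none rose (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.094). COL1A1 went from 613 ± 9.29 to 134 ± 40.6 FPKM (log2 fold change −2.23 ± 0.26 SE, adjusted p = 0.0011). ACTA2 went from 255 ± 23.7 to 111 ± 22.2 FPKM (log2 fold change −1.21 ± 0.20 SE, adjusted p = 0.00358). The list passed without control replicate 2 (camera adjusted p = 0.0376), after quantile normalization (0.00921) and without a low-value filter (0.0288). Of 6 epithelial markers tested ELF3 (1.27) and CLDN4 (0.74) rose and KRT18 fell, and CLDN4 had adjusted p = 0.0881 without control replicate 1, 0.122 without control replicate 2 and 0.057 without a low-value filter. No leukocyte marker reached 1 FPKM in any library, the highest value being 0.373 FPKM. Few members of the endothelial (3), neural and neuroendocrine (4) and theca and stroma (4) lists could be tested, too few for the list test. Of these, KDR rose and TEK and ENG fell, none of the 4 neural genes passed, and ACTA2 and NR2F2 fell. NR2F2 had adjusted p = 0.074 without control replicate 1 and 0.0606 without control replicate 2.

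Of 320 list members called, 168 lost the call without control replicate 1, 140 without control replicate 2, and 10, 55 and 44 without 3-NP replicates 1, 2 and 3. Leaving out either control also left 13 of them under the low-value filter and not tested, so the counts per list depend on having 2 controls. In total camera called 15 of 37 lists, 10 higher and 5 lower, with a preset correlation of 0.01 between genes. No list passed with an estimated correlation, for which the smallest adjusted p was 0.366, and 3 lists had an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move one way on balance, called 15 lists, 10 of them among those of camera. It did not call G2/M and mitosis (fry adjusted p = 0.0624), ribosomal proteins (0.284) or nuclear-encoded OXPHOS subunits (0.52), which camera called. Nor did it call other antioxidant enzymes or FOXO targets (both 0.0502). Fry alone called complex II, hypoxia-inducible factor targets and fatty acid oxidation higher (each 0.0433). It alone called aminoacyl-tRNA synthetases and extracellular matrix and mesenchymal genes lower (each 0.0433). Median, mean and camera direction differed in sign for lists that included granulosa markers, glycolysis, fatty acid synthesis, epithelial markers and mitochondrial biogenesis, none of which camera called.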

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

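The settings of equal FPKM totals, median-of-ratios scaling, robust moderation, protein-coding genes only, voom, and removal of length or length and GC trends were chosen after the results had been seen. None of the 113 named genes or 37 lists changed direction with a call in any setting. Of the genes, 81 kept their side of the threshold in all settings in which they were tested, 31 lost the call in at least 1 setting and 1 gained it. Of the lists, under camera with the preset correlation, 26 kept theirs in every refit, 4 lost it in at least 1 setting (nuclear-encoded OXPHOS subunits, other antioxidant enzymes, FOXO targets and heat shock) and 7 gained it. All 15 called lists lost the call with an estimated correlation, and fry called 10 of the 15. Most losses of genes came from leaving out a control, which leaves a single control assumed to vary like the 3-NP libraries: 27 without control replicate 1 and 21 without control replicate 2. With a library left out, genes higher ranged from 752 to 2147 and genes lower from 1062 to 3107. Without control replicate 1, 752 were higher and 1062 lower, and without control replicate 2, 909 and 1179; of the 4833 calls, 1803 and 2062 were called again in the same direction, and 444 were not tested in each of these fits because they reached 1 FPKM in fewer than 2 of the remaining libraries.

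Genes at least 2-fold higher numbered 1009 and at least 2-fold lower 1554 with a pseudocount of 0.1, and 908 and 1522 with voom. A smaller pseudocount enlarges the fitted change of low genes by construction. Voom adds less than 1 read before the log, and 1 read on a gene of 2 kb was 0.0265 to 0.028 FPKM. That is far below the 1 FPKM added in the main fit, so voom enlarges these changes too. Whether this makes up its whole difference from the main fit was not tested. Lists called lower numbered 9 after quantile normalization and 8 without a low-value filter, against 5, and the cause was not tested. With an estimated correlation 0 lists were higher and 0 lower, where p under 0.05 before adjustment was reached by 3 lists and fry called 15. The estimated correlations reached 0.907, for ribosomal proteins, and a high correlation widens camera's error. They were below the preset 0.01 for heat shock (−0.0513), cholesterol synthesis (−0.0221), NF-kB (−0.0181) and WNT and NOTCH targets (−0.0566). These lists lost the call too, so high correlation was not the only reason, and the loss is not read as a sign of it. The share of calls that were lower was 61.89%, against 52.04% after quantile normalization, 52.56% with median-of-ratios scaling, 51.73% and 51.83% with the length or the length and GC trends removed, and 68.93% with equal FPKM totals. The median log2 fold change of all genes was −0.11, −0.017, −0.019, −0.019, −0.016 and −0.2 in the same order. Whether scaling made the excess of lower calls was tested with median-of-ratios scaling, with the prediction that a share of 45% to 55% would point to scaling. The share met it, but that scaling centres the genes by construction, so the test does not separate a real excess from scaling, and it is not weighed further.

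With the replicate number as a block, 1737 genes were higher and 2610 lower, and camera's adjusted p was 0.133 for nuclear-encoded OXPHOS subunits and 0.00619 for extracellular matrix and mesenchymal genes. Among named genes, the block ended the calls of SDHB (limma adjusted p = 0.0853), NDUFS1 (0.0604), FUNDC1 (0.124), ETFA (0.0713) and SCARB1 (0.0986). Deviations from the group means correlated at 0.157 between libraries numbered 1 and at −0.352 between libraries numbered 2, while control replicate 2 went with 3-NP replicate 3 at 0.469, so the numbers were not taken to pair the samples. Parts of the plan that need counts (other size factors, library totals alone, a negative binomial test and its robust form) were not run on these FPKM files. Depth limits statements on genes under about 0.08 FPKM at a length of 2 kb, and at higher levels for shorter genes.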

Other observations

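The genes and families in the first paragraphs, and the test of ribosomal levels between libraries, were chosen after the values had been seen; the length and scaling tests were set after the main results but before their own outcomes were computed. Gene families were formed from the letters before the first digit of a protein-coding symbol (a second, looser stem had been looked at first), and 172 families of 8 or more tested genes gave 344 one-sided Fisher's exact tests for higher and lower calls. Of 32 DDX helicases 21 fell and none rose (adjusted p = 0.000858), of 31 RBM proteins 19 fell and 1 rose (adjusted p = 0.0055), and of 11 SRSF splicing factors 9 fell (adjusted p = 0.0141). SRSF1 went from 30.9 ± 0.446 to 4.17 ± 0.22 FPKM (log2 fold change −2.63 ± 0.13 SE, adjusted p = 0.000105). SRSF6 went from 23.2 ± 2.67 to 5.13 ± 0.422 FPKM (log2 fold change −1.98 ± 0.14 SE, adjusted p = 0.000287). DDX6 went from 10.3 ± 1.7 to 3.21 ± 0.619 FPKM (log2 fold change −1.42 ± 0.18 SE, adjusted p = 0.00152). Genes with the stem MCM, which include MCM10 and MCM3AP beside helicase subunits (8 of 9 lower, adjusted p = 0.0141), and ARHGEF exchange factors (11 of 16 lower, adjusted p = 0.0219) also passed, as did ZNF genes (79 of 223 lower, 18 higher, adjusted p = 0.0409) and, among rises, DUSP phosphatases (9 of 17 higher, 4 lower, adjusted p = 0.0219). The background was 25.8% of 10603 genes lower and 15.5% higher. Fisher's test treats the genes of a family as independent, though all were measured in the same 5 libraries. Where members move together its p-values are too small. No estimated correlation was applied to families, so they are not better supported than the gene lists. Median changes kept their sign in each family under quantile normalization, equal totals, median-of-ratios scaling and removal of length or length and GC trends, but with p adjusted over all families in each setting, only DDX and MCM passed in all 5 of these (adjusted p = 0.0455 at most). SRSF passed in all but the removal of length and GC trends (0.0904). RBM, DUSP and ZNF passed only with equal totals (0.00389, 0.0105 and 0.0086), with adjusted p in the others of 0.176 to 0.525, 0.0897 to 0.234 and 0.253 to 1, and ARHGEF passed in none (0.0813 to 0.69).

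KEAP1, the inhibitor of NRF2, went from 21.2 ± 2.24 to 4.98 ± 0.465 FPKM (log2 fold change −1.89 ± 0.14 SE, adjusted p = 0.000318). HBEGF, a ligand of the EGF receptor, went from 5.58 ± 0.121 to 62.5 ± 12.8 FPKM (log2 fold change 3.25 ± 0.19 SE, adjusted p = 0.000179). ERRFI1, a feedback inhibitor of this receptor, went from 22.4 ± 2.32 to 264 ± 93.2 FPKM (log2 fold change 3.45 ± 0.27 SE, adjusted p = 0.000344). SAT1, an enzyme of polyamine catabolism, went from 40.6 ± 2.13 to 463 ± 114 FPKM (log2 fold change 3.45 ± 0.23 SE, adjusted p = 0.000241). SMOX, which oxidises spermine, went from 1.79 ± 0.247 to 14.9 ± 2.61 FPKM (log2 fold change 2.51 ± 0.18 SE, adjusted p = 0.000254). CDKN2A, H19 and FOLR1 did not pass (adjusted p = 0.849, 0.932 and 0.62), and their 3-NP libraries lay on both sides of the controls. CDKN2A stood at 4.64 and 6.41 FPKM in the controls and at 0.673, 13.7 and 17.4 FPKM in 3-NP replicates 1, 2 and 3, H19 at 12.6 and 15.3 against 0.956, 30.1 and 39.5 FPKM, and FOLR1 at 31 and 43.9 against 9.91, 126 and 166 FPKM. KRT14 lay between 682 and 1004 FPKM in all libraries, where KRT5 was at most 0.0247 FPKM. FSHR, CYP19A1 and WT1, which granulosa cells or their tumours often express, did not exceed 0.0753 FPKM in any library. The granulosa marker INHA lay between 0.0604 and 0.512 FPKM and was under the low-value filter. FOXL2 was detected, and AMH lay near the filter limit, at 0.866 to 1.23 FPKM.

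The rise of the ribosomal protein list was set against 2 technical explanations. With the length trend removed its median change was 0.465, against 0.445 before (quartiles 0.381 to 0.566 and 0.329 to 0.573, camera adjusted p = 2.2e-05 after). The list's median exon-union length was 3667 bases, against 4720 over all genes tested, so the removal could move it little. Lengths of the transcripts expressed were not used, so an effect of these stays open. The controls differed from each other with length (Spearman −0.467 across genes), more than 3-NP from control (−0.146). With GC content the controls differed at 0.537 and 3-NP from control at 0.032. Differences between 3-NP libraries ran with GC content at −0.357 to 0.52. Between libraries, the lowest 3-NP library lay 0.03 below the higher control (a gap of −0.03 in the list's median log2 level), so the rise is consistent with spread between libraries of 1 group. That spread stays open, and the rise is not read as a response.

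The fall of the 2 cell cycle lists was also set against 2 technical explanations. With the trend with exon-union length removed the mean of their medians was −0.97, against −1.04 (camera adjusted p = 2.2e-05 at most after removal). Their median lengths of 4147.5 and 3933.5 bases lay near the 4720 of all genes tested, so the removal could move them little. A trend with the length of the transcripts expressed was not tested. Over the fits that left out 1 library the largest camera adjusted p was 0.00144, which argues against a single library as the source. Culture density, dose and time are not in the labels, and no biological explanation was tested. With an estimated correlation the lists did not pass (adjusted p = 0.628 and 0.634). By fry, G1/S and DNA replication passed (adjusted p = 0.0433) and G2/M and mitosis did not (0.0624).

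The rise of the immediate early list was likewise weighed. Its median was 1.57 with the length trend removed, against 1.43, and at least 1.37 under the 3 other scalings (quantile normalization, equal totals and median-of-ratios). A trend with exon-union length thus does not account for it, and one with the length of the transcripts expressed was not tested. Median-of-ratios factors ran only from 0.9585 to 1.058, so the scaling test could hardly have failed. Such differences in scaling are too small to make a median of 1.43. These genes also respond to handling, such as a change of medium or the harvest, and whether both groups were handled alike is not given in the labels. A response to 3-NP and a difference in handling may each produce this pattern, and no value here separates them. With an estimated correlation the list had adjusted p = 0.366.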
